A study of Arabidopsis thaliana with 6 samples.

How the data were processed

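RNA from excised hypocotyls of 6-day-old Arabidopsis thaliana seedlings was hybridised to single-channel Affymetrix arrays, 1 array per sample. Per the labels' protocols, 300 ng of total RNA per sample was labelled with biotin by a 3' in vitro transcription kit. The deposited values are linear signal intensities per probe set, made with MAS5 in Affymetrix Expression Console 1.1, per the submitters' processing notes. On each array the mean intensity of the deposited values was 500 after the lowest and highest 2% of probe sets were trimmed, as computed from the values. Such scaling fixes that trimmed mean on every array, so log2 changes are relative to it. Detection calls and scanner images were not used here. The number of arrays, 3 per group, limits the precision.

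The table held 22810 probe sets, of which 64 were control probe sets and were left out of the tests. Of the other 22746, the platform annotation used here listed 1 gene for 13513, several genes for 503 and none for 8730. Only single-gene probe sets were named, and 13436 of them matched a gene of the TAIR10.1 gene table by gene ID. That table was used for names and for the order of neighbouring genes. No coordinates are given, since the build behind the platform annotation is not given in the sources used here.

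Intensities were put on the log2 scale without a pseudocount and with the authors' scaling kept. The 60% of non-control probe sets with the highest mean over the 6 arrays were tested, 13648 in all. The lowest mean kept was 6.06 on the log2 scale, a geometric mean signal of 66.6. The groups, shr minus Col-0, were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, no covariates). Every adjusted p is Benjamini-Hochberg adjusted, with a threshold of 0.05, and errors of log2 changes are limma's moderated standard errors. The fit was tested on simulated arrays of 13648 probe sets for this comparison. It recovered 28%, 68%, 92% and 98% of probe sets changed by 0.5, 1, 2 and 3 log2 units, with 2 false calls among 145. Only 50 probe sets were changed at each size there, a far smaller share than was called in the data. These rates therefore need not hold for the real comparison.

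Before the data were examined, 39 gene lists, the design, the rule for named genes and most alternatives were fixed. Of the 1336 places in these lists that matched a gene, 182 (13.6%) had a named probe set, so each list is covered only in part. Symbols that the table gave to another gene were left out at 3 places in the lists. Lists with at least 5 tested genes, 8 in number, were tested with camera, with a preset inter-gene correlation of 0.01 and 1 probe set per gene, the brightest. The count of members past the threshold was taken over all probe sets tested and again within each list.

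Named genes were the 10 largest rises and 10 largest falls among single-gene probe sets past the threshold with no overlap between groups. To these came, for each list, at most 4 members past the threshold in order of adjusted p, or at most 2 with the smallest p where none passed. Genes named outside this rule are marked as chosen after their values were seen. The rule also called for SHR itself, but no probe set was named as SHR in the annotation used here, so its level is not analysed here and the genotype labels were not checked against it.

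Additions were made later. A set of 20 families was defined from gene symbols and the plastid and mitochondrial genomes once the data were open but before any fit, and 18 were large enough for camera. After the largest changes had been seen, 31 list symbols absent from the gene table were placed by locus tag from general knowledge, of which 21 had a named probe set. Each of these sets of lists was adjusted among itself.

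Alternatives were no filter, a filter at the highest 40%, quantile normalization, centring each array on its median, log2(signal + 32), eBayes without the trend, array weights, the replicate number as a block, leaving out each array, and 2 thresholds with a 2-fold minimum. For lists, camera with an estimated correlation, fry and the mean of a gene's probe sets were also run. Python 3.11.15 with scipy 1.17.1 was used for permutation and Fisher's exact tests.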

Results

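Gene expression was measured in hypocotyls cut from 6-day-old seedlings, germinated for 24 hours and then kept in the dark for 5 days. Samples came from 3 biological replicates of the Columbia wild type (Col-0) and 3 of shr-2, a loss-of-function mutant of SHORT-ROOT (SHR), a GRAS transcription factor known for specifying the endodermis. Pearson correlations of log2 signal across probe sets were 0.920 to 0.928 among Col-0 arrays, 0.947 to 0.948 among shr arrays and 0.888 to 0.907 between the groups. The single comparison the design gives is that of mutant and wild-type hypocotyls. No probe set was named as SHR, so the transcript of the mutated gene is not analysed here.

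The peroxidase gene PRX72, of the endodermal Casparian strip list, and 3 of the 4 tested SHR-SCR network genes were lower in shr than in Col-0. PRX72 (AT5G66390) fell 27.9-fold (log2 change -4.80 ± 0.091 SE, n = 3 per group). TRI (AT2G29330), named as tropinone reductase, fell from a mean log2 signal of 8.18 ± 0.046 (SD) to a dim 5.13 ± 0.76, and the zinc finger gene JKD (AT5G03150), whose product works with SHR, fell 1.83-fold. Nuclear photosynthesis genes were mostly higher in shr, among them the rubisco activase gene RCA, which rose 2.87-fold. Cell wall genes changed in both directions, with EXPA9 and XTH32 up 5.66-fold and 6.61-fold and XTH18 down 3.13-fold.

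Of 13648 probe sets tested, 7215 (52.9%) had an adjusted p under 0.05 in limma, 4368 higher and 2847 lower in shr. At least 2-fold changes with the same adjusted p were found for 1334 probe sets higher and 799 lower, and at least 8-fold ones for 40 and 59. The 2-fold counts were 1027 higher and 920 lower after quantile normalization and turned to 864 higher and 1200 lower after median centring. Single-gene probe sets covered 7302 genes, of which 3740 had a called probe set. The split depended on array scaling. Of the calls, 60.5% were higher in shr with the authors' scaling, 52.3% (3665 higher, 3349 lower) after quantile normalization and 42.8% (2926 higher, 3908 lower) after median centring. The median log2 change over all tested probe sets was 0.13, 0.016 and -0.066 under these scalings, so median centring lowered every log2 change by 0.20.

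Among the 10 largest falls, AT4G02090 had the largest, with a mean log2 signal of 11.23 ± 0.11 (SD, n = 3) in Col-0 and 4.75 ± 1.54 in shr (log2 change -6.48 ± 0.50 SE, adjusted p = 1.20e-07). Next came AT4G11290 (-5.39), AT2G04800 (-4.84), PRX72 (-4.80), AT1G30750 (-4.79), AT1G61590 (-4.77) and AT4G13580 (-4.68). AT1G71740 (-4.61), AT1G14580 (-4.53) and AT5G26270 (-4.52) completed the set. AT4G13580 went from a mean log2 signal of 13.72 ± 0.058 in Col-0 to 9.05 ± 0.17 in shr.

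The 10 largest rises were led by AT5G50335, with a log2 change of 5.43 ± 0.78 SE from a low and variable Col-0 signal (3.88 ± 2.31, SD, n = 3). AT5G19100 rose from 6.81 ± 0.073 to 12.21 ± 0.16 (log2 change 5.40 ± 0.11 SE, adjusted p = 1.20e-13). AT2G15560 (5.20), AT1G53080 (4.91), AT3G02480 (4.47), M10 (4.38), ATC (4.36), AT2G47780 (16.0-fold) and AT5G15950 (3.85) followed. ATC is a homologue of the flowering repressor CENTRORADIALIS. GH9B13, a family 9 glycosyl hydrolase, rose 13.8-fold to a mean log2 signal of 12.41 ± 0.027. The lower group's mean lay below the lowest mean signal kept, 6.06, for 5 of the 10 rises and 2 of the 10 falls, so those folds rest on dim probe sets. The same held for 9 of the 85 list members that the rule names, among them TRI, FACT, WSD1, DPE1, LBD29, BCAT4 and EXPA18.

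In the list of SHR-SCR network genes, 4 members were tested, of which 3 fell and 1 rose. TRI fell by 3.05 ± 0.34 on the log2 scale, SCL23 (AT5G41920), a GRAS relative of SCARECROW, by 1.18 ± 0.30 and JKD by 0.87 ± 0.22. PHV, a class III HD-ZIP gene of radial patterning, rose by 0.76 ± 0.11. The Casparian strip list, for the lignified seal between endodermal cells, had PRX72 as its 1 named and tested member. Placing list symbols by locus, done after the largest changes had been seen, added AT4G11290 (as PER39), AT1G61590 (as SGN1), AT1G44970 (as PER9) and GSO1 (as SGN3). All 5 members then fell, including AT1G44970 (-4.17 ± 0.15) and GSO1 (-2.98 ± 0.18), which was named outside the rule after its value was seen. Camera gave the completed list an adjusted p of 3.49e-08, and an adjusted p of 0.0415 with an estimated correlation. With quantile normalization as well as an estimated correlation the adjusted p was 0.0512. Since 2 of the added genes were already among the largest falls, this p is not independent of the data. Placement by locus also put AT1G14580 (as BLJ), a relative of JKD, among the network genes.

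**Figure D1:**
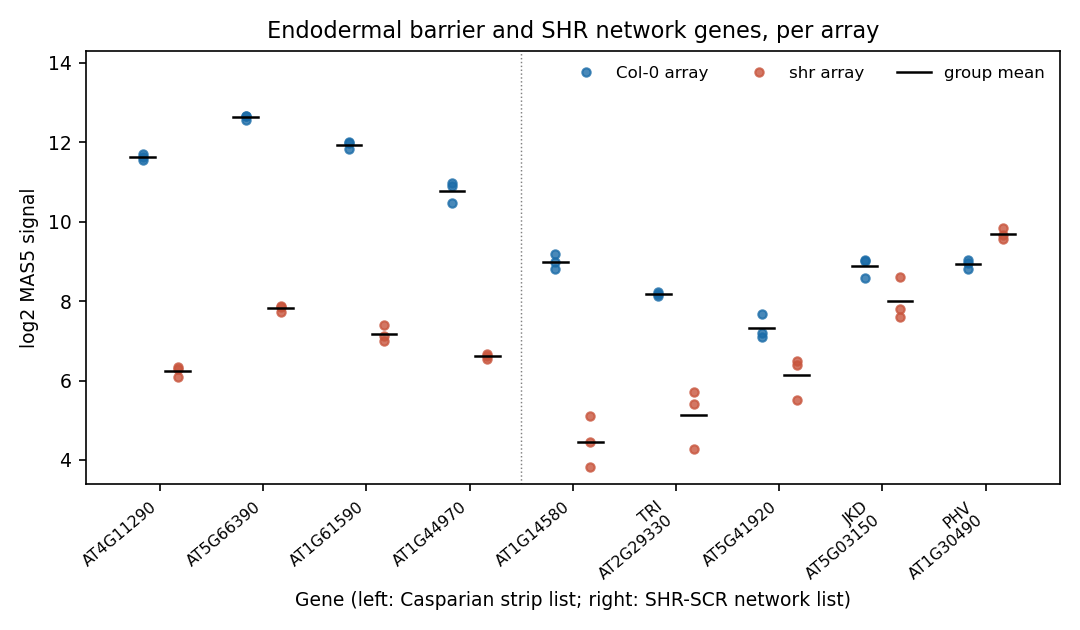
Log2 MAS5 signal (vertical axis) on each of the 3 Col-0 and 3 shr arrays for the Casparian strip genes with the 4 smallest adjusted p (left) and SHR-SCR network genes (right), with group means as bars; some members were placed by locus after the largest changes had been seen. The log2 changes of the 4 barrier genes ran from -5.39 to -4.17, while PHV was higher by 0.76.

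Other lists of barrier lipids and lignin had few named members. The suberin gene FACT, a fatty alcohol caffeoyl transferase, fell by 1.18 ± 0.35, and AT2G48130, placed by locus as LTPG15, fell by 3.77 ± 0.11. WSD1, a wax ester synthase and the 1 tested gene of cutin and wax, fell by 2.65 ± 0.28. Of 3 lignin and phenylpropanoid genes, CCR2 fell by 1.69 ± 0.20 and HCT by 0.33 ± 0.079, and 1 did not pass. The call of HCT was lost after quantile normalization. None of 3 xylem and secondary wall genes passed, with GUT2 at -0.17 ± 0.11 and PRX52 at -0.17 ± 0.13, while PRX52 was called lower under both other scalings, GUT2 after median centring and the remaining member after quantile normalization. Phloem genes split, with SWEET11 (-0.90 ± 0.088) and CLE44 (-0.97 ± 0.18) lower and CLE41 (0.68 ± 0.12) and OPS (0.66 ± 0.15) higher.

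Of 10 nuclear photosynthesis genes, 8 rose, 1 fell and 1 did not pass. PSBW, of photosystem II, rose by 1.71 ± 0.12, RCA by 1.52 ± 0.12 and the Calvin cycle gene SBPASE by 2.23 ± 0.18. The list was shifted upward in camera (adjusted p = 0.00592), the 1 fixed list of 8 to pass, but its adjusted p was 0.195 with an estimated correlation. After median centring 6 of the 10 were called higher. Of 8 chlorophyll synthesis genes 3 rose, led by the protochlorophyllide oxidoreductase gene PORB (1.39 ± 0.11), 1 fell (GSA1, -0.39 ± 0.10) and 4 did not pass (camera adjusted p = 0.315). Of 8 oxidative stress genes, 5 rose and 1 fell (camera adjusted p = 0.282), all of them tau glutathione transferases. GSTU25 rose by 2.49 ± 0.16 and GSTU26 fell by 0.77 ± 0.092. Quantile normalization and median centring each called 3 of these 8 lower.

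Expansins, which loosen growing walls, were 5 higher, 5 lower and 4 not past the threshold of 14 tested (camera adjusted p = 0.897). EXPA9 rose by 2.50 ± 0.12 and EXPA8 by 0.95 ± 0.079, while EXPA4 fell by 0.84 ± 0.086. Xyloglucan endotransglucosylases were 3 higher, 3 lower and 1 not past the threshold (camera adjusted p = 0.854). XTH32 rose by 2.73 ± 0.12 and XTH16 by 1.43 ± 0.12, and XTH18 and EXGT-A3 fell by 1.65 ± 0.084 and 1.54 ± 0.083. The receptor kinase genes THE1 (-0.73 ± 0.10) and FER (-0.51 ± 0.076), both tested under primary wall cellulose synthesis, were lower. Pectin methylesterase genes PME61 (-0.71 ± 0.10) and ATPMEPCRB (-0.73 ± 0.19) were lower too.

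Of 8 auxin response genes 1 rose and 4 fell (camera adjusted p = 0.282). GH3.3 rose by 1.25 ± 0.095, while the related auxin-conjugating genes WES1 and GH3.17 fell by 0.84 ± 0.085 and 0.73 ± 0.11 and LBD29 fell 4.29-fold. Auxin synthesis and transport genes YUC2 (-0.88 ± 0.17) and WAG2 (-0.36 ± 0.086) fell, of 3 tested. In the gibberellin list of 6, the receptor genes GID1A (-0.56 ± 0.098) and GID1C (-0.53 ± 0.13) fell and SEC (0.40 ± 0.13) rose, with 3 not past the threshold (camera adjusted p = 0.370). The call of SEC was lost under both other scalings, without Col-0 replicate 1 (0.33) and without shr replicate 2 (0.32). Under those scalings none of the list was called higher, while 3 were lower after quantile normalization (with SLY1) and 4 after median centring (with SLY1 and GID1B, both named after their values were seen). Both tested ethylene genes, EIN3 (0.69 ± 0.14) and RTE1 (0.35 ± 0.13), were higher, though RTE1 lost its call under both other scalings, with eBayes without the trend, without Col-0 replicate 1 (0.22), and without shr replicate 2 (0.37) or 3 (0.31). BRL1, the tested brassinosteroid gene, had a log2 change of 0.43 ± 0.23 and did not pass.

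Of 8 genes in the sugar starvation and trehalose list, 4 fell and 1 rose (camera adjusted p = 0.179). The vacuolar sugar transporter genes SWEET16 and SWEET17 fell by 2.04 ± 0.097 and 1.44 ± 0.097. Both tested starch genes of the gravitropism list rose, SBE2.2 by 1.51 ± 0.23 and DPE1 by 1.47 ± 0.27. Of 4 seed storage genes 3 rose, isocitrate lyase (ICL) by 2.29 ± 0.086, the oleosin gene OLEO3 by 2.04 ± 0.14 and LEA4-5 by 1.17 ± 0.20, while the lipase gene SDP1 fell by 0.38 ± 0.11. All 3 tested glucosinolate genes rose, including BCAT4 (1.57 ± 0.27) and UGT74B1 (0.64 ± 0.15). The endoreduplication gene SIM fell by 0.82 ± 0.11. Cell cycle genes AUR2 (-0.57 ± 0.14) and AUR1 (-0.43 ± 0.12) fell, and PRL (0.56 ± 0.16) rose with a call that both other scalings removed. Under root tissue, HRGP1 (1.57 ± 0.11) and EXPA18 (2.06 ± 0.52) rose and PYK10 fell by 0.50 ± 0.072. After quantile normalization PYK10 lost its call and changed sign, with a log2 change of 0.088.

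**Figure D2:**
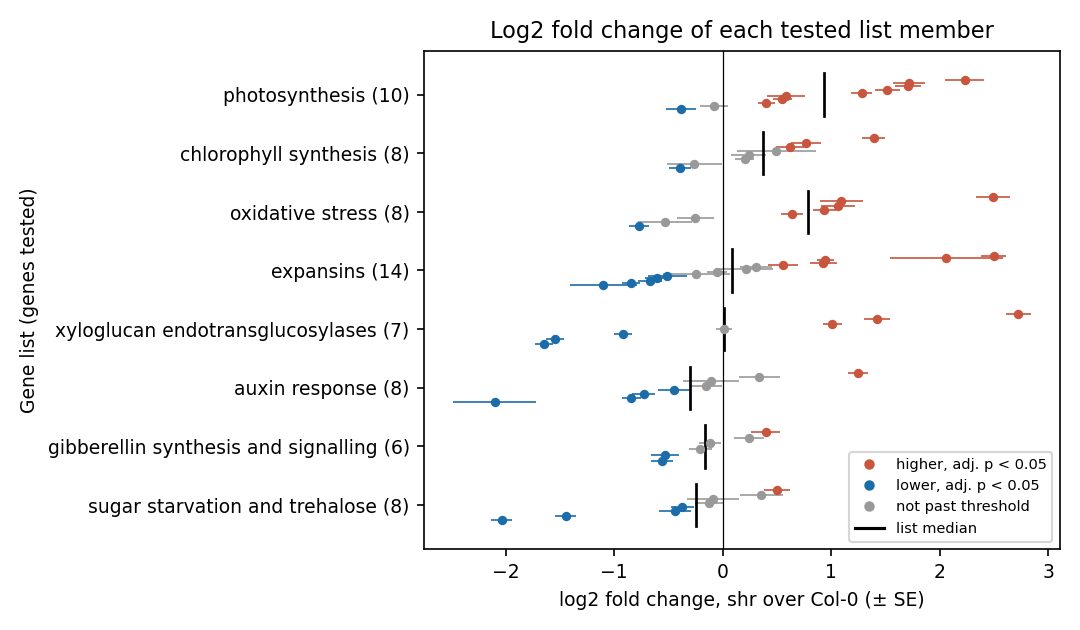
Log2 fold change of shr over Col-0 (horizontal axis, points with SE bars from limma, 3 arrays per group) for each tested member of the 8 gene lists large enough to test, with list medians as black bars. The photosynthesis median was 0.93 and that of expansins 0.084, with expansins on both sides of 0; the expansin median was -0.11 after median centring.

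Over the 34 lists with a tested gene, 128 genes were tested, 47 higher, 45 lower and 36 not past the threshold. Calls were thus made for 71.9% of list genes, against 51.2% of all tested genes. A list with a share of calls near 51.2% shows no excess over that background. Counts adjusted over the list alone equalled those over all probe sets in each fixed list except salicylic acid and pathogen response, where SAG101 (0.81 ± 0.30) was 1 call of 3 over all probe sets and 0 over the list alone. SAG101 also lost its call with no filter, under both other scalings and without any of Col-0 replicate 1 (0.56) or 2 (0.82) and shr replicate 2 (0.77) or 3 (0.73). Reference genes ranged from -0.28 (PEX4) to 0.48 (TUB6), the most changed, with TUB6 and PEX4 past the threshold. PEX4 lost its call after quantile normalization (-0.19), with eBayes without the trend, without Col-0 replicate 1 (-0.24) and without shr replicate 2 (-0.21). GAPC2, named after its values were seen, was uncalled at -0.084 but called higher after quantile normalization (0.42) and lower after median centring (-0.28).

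The arrays also differed in their signal distribution. The 100 brightest probe sets held 19.1% ± 0.54 (SD, n = 3) of the signal on Col-0 arrays and 14.2% ± 0.18 on shr arrays, and the median signal was 106 to 117 and 125 to 130. Hybridisation spikes differed by -0.58 log2 units on shr arrays against Col-0 arrays. The exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. The 3'/5' signal ratio of actin was 4.91 ± 0.10 in Col-0 and 4.35 ± 0.50 in shr, with overlapping arrays. That of ubiquitin was 1.22 ± 0.0645 in Col-0 and 1.38 ± 0.11 in shr, without overlap (1.14 to 1.27 against 1.28 to 1.51), and that of glyceraldehyde-3-phosphate dehydrogenase was 1.21 in both.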

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

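Control probe sets took no part in the limma and camera tests above, and those for plant genes were compared after the main result was known. Among the 19 plant control probe sets, 4 were higher on every shr array than on any Col-0 array, and all 4 were for glyceraldehyde-3-phosphate dehydrogenase. The shr signal was 1.75-fold and 1.53-fold that of Col-0 for the 5' and middle probe sets of the older design. The newer design's 3' and 5' probe sets gave 1.26-fold and 1.25-fold. Another 10 of the 19 were lower on every shr array, where chance gives 5% in each direction. Such separation was common here, as 96.7% of called and 18.3% of uncalled tested probe sets had no overlap. Of 18 hybridisation spikes 17 were lower on every shr array, and of 24 B. subtilis labelling spikes 12 were, with none higher.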

How the results depend on the processing

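The lists completed by locus and the families were added after the data had been opened, and all other settings here were planned. The count of 7215 changed probe sets stayed within 1.5 times under each filter, scaling and variance setting. The share called depended on the filter, at 52.9% in the main fit, 31.9% of 22746 with no filter and 64.3% of 9098 with the highest 40%. Leaving out each array gave 6226 to 7124 calls, with 3682 to 4424 higher and 2544 to 2725 lower. By construction, a 2-fold minimum left 2133 (1334 higher, 799 lower), and 2148 (1349 higher, 799 lower) with an unadjusted p, and the 2-fold split turned after median centring (864 higher, 1200 lower). Of the calls, 86.4% were shared in direction with quantile normalization and 80.0% with median centring. The replicate numbers gave no sign of pairing. Correlations of deviations were -0.080, 0.018 and -0.016 between same-numbered arrays and -0.069 to 0.079 between others. This cannot show whether samples were grown or processed in pairs. With the replicate block, 6962 probe sets were called.

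The number of fixed lists shifted was 1, and leaving out any array gave 1. It was 2 with no filter, 0 with an estimated correlation, 6 with fry and 2 with lists completed by locus. Fry tests a list against no change and not against other genes; no other cause was tested. UDP-glycosyltransferases, down in camera (limma adjusted p = 0.931), were up in fry, with 0.0073 unadjusted and 0.0119 adjusted. Of 101 named genes called, 10 lost the call in at least 1 setting. PYK10 (-0.50) lost its call after quantile normalization and changed sign, to a log2 change of 0.088 (limma adjusted p = 0.287). It was the 1 called named gene to change sign in any setting. PYE, of the iron list, was uncalled at 0.073. It became -0.13 after quantile normalization, -0.12 after median centring and -0.065 to 0.16 when each array was left out. The cause was not tested. SHR gave no value under any setting. Without detection calls, signal over background could not be judged, which limits folds of dim probe sets.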

Other observations

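The gene families were defined once the data were open, and the tests of plastid genes, of the share of higher calls, of seed genes and of barrier genes under other scalings were chosen after their results were seen. The test of SHR's neighbours and the splits of the arrays were planned before. Of 18 families tested with camera, plastid-encoded genes and SWEET transporters passed. Of 6 SWEET sugar transporter genes 4 fell, with SWEET3 at -3.74 ± 0.16 (SE, n = 3 per group), and none rose. Quantile normalization gave the same counts. So did median centring, but it lowers every log2 change alike and could not have removed these falls or added a rise. The family's adjusted p was 0.00406, and 0.205 with an estimated correlation. Of 58 tested genes of the plastid genome 46 rose and none fell, with rpoC1 (2.53 ± 0.12) and rpoA (2.44 ± 0.12), for the plastid RNA polymerase, the ribosomal protein gene rps3 (2.21 ± 0.12) and clpP (2.42 ± 0.15) first by adjusted p. SWEET3 and these plastid genes were chosen after their values were seen. The family's adjusted p was 9.59e-11, and 0.205 with an estimated correlation. After quantile normalization 40 were higher and 1 lower, and after median centring 34 and 3.

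Other families were not shifted as sets, though single members moved far. The tubulin gene TUB1 rose by 3.28 ± 0.085 and TUA1 fell 2.15-fold, and of 7 tubulins 3 rose and 1 fell (adjusted p = 0.435), with 5 higher after quantile normalization. All 6 RALF-like peptide genes were called, 3 in each direction (adjusted p = 0.639), with RALFL34 up by 1.36 ± 0.10 and RALFL22 down by 1.24 ± 0.081. After median centring 2 of them were higher. Of 9 GH9 endoglucanases 3 rose and 2 fell (adjusted p = 0.513; 4 and 1 after quantile normalization), GH9B8 by 2.24 ± 0.14 beside GH9B13. UGT72E3 fell by 3.78 ± 0.31 while UGT87A2 rose by 2.33 ± 0.14. These members were chosen after their values were seen.

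The rise of plastid-encoded transcripts was weighed against 3 explanations. Array scaling alone would bring their median log2 change near 0 under another scaling. Median centring lowers every log2 change alike by 0.20, so the median of 0.88 was bound to become 0.68. Quantile normalization, which is not a constant shift, gave 0.90. Neither of these scalings removed the rise, and other scalings were not tried. More labelling of RNA without a poly(A) tail would raise mitochondrion-encoded genes alike, but these had a median of -0.20 over 12 genes, 1.07 below the plastid median (two-sided permutation p = 8e-05, genes not being independent). More cotyledon tissue in the excised shr samples may account for part of it, since the 10 nuclear photosynthesis genes had a median of 0.93. The reserve genes ICL (2.29 ± 0.086) and OLEO3 (2.04 ± 0.14) and STOMAGEN (1.68 ± 0.19), of the epidermis list, rose as well, though the seed lipase gene SDP1 fell by 0.38 ± 0.11. Without the filter, the epidermis list of 4 genes had 1 higher, none lower and a median of 0.0010. The shoot apex and leaf list, with 5 genes measured when no filter was used, had 1 higher, none lower and a median of -0.52 (camera adjusted p = 0.938). Tissue content and expression within the hypocotyl cannot be told apart here, because no cotyledon sample was used, and an effect of the genotype stays open as untested.

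The excess of higher over lower calls could come from array scaling, as the share of higher calls was 60.5% with the authors' scaling, 52.3% after quantile normalization and 42.8% after median centring. Both other scalings lowered the median log2 change, and no scaling to the spikes was run. Hybridisation and labelling spikes differed by -0.58 and -0.45 log2 units on shr arrays against Col-0 arrays. Scaling to the spikes would thus move log2 changes upward, opposite to both other scalings. Small falls may therefore depend on the scaling as much as small rises, which was not tested. Whether more transcripts truly rose than fell stays open.

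Calls near the mutated gene were tested because variants or a rearrangement linked to SHR on chromosome 4 could add calls among its neighbours. Of the 100 tested genes before SHR and the 79 after it, up to the end of the chromosome, 48.0% were called, against 51.3% of other tested genes. The odds ratio was 0.878 (95% interval 0.644 to 1.19, Fisher's exact test p = 0.406), which argues against a large excess of calls there.

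Barrier genes of the completed Casparian strip list all had a log2 change of -3.05 or lower under quantile normalization and median centring. Median centring lowers every log2 change alike, so it could not have removed these falls. Without the filter, seed storage genes were tested as a sign of a different developmental stage or more reserve tissue. They rose with an adjusted p of 0.0395 in camera, and 0.329 with an estimated correlation, which leaves that hypothesis undecided. The real grouping of the 6 arrays gave 7215 changed probe sets and the highest of the other splits 0, so 1 of 10 splits gave as many. That is too few splits for a share under 0.05. Every other split also mixes Col-0 and shr arrays within its groups, which widens the spread there. Few calls were then bound to follow, so the 0 does not show how many calls chance would give.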
